A study of Mus musculus with 15 samples.

How the data were processed

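Messenger RNA of forelimb joint tissue was sequenced in 15 libraries from male DBA/1 mice aged 8 weeks, 5 each from non-immunized mice (healthy), mice with collagen-induced arthritis (CIA) and mice with collagen-induced arthritis given the compound F20 (CIA+F20). Per the labels' protocols, the forearm, wrist and paw were kept, skin and surplus muscle were taken off, and the capsule, synovium and soft tissue around the joint were left in place before snap-freezing. Polyadenylated RNA was selected, and paired-end reads came from an MGI instrument, per the labels' protocols. Neither the vehicle given to the CIA group nor the hour of sacrifice is stated in the sources used here.

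Per the submitters' processing notes, reads were trimmed with fastp 0.23.2, aligned to the mouse genome GRCm39 with HISAT2 2.2.1 and counted per gene with featureCounts 2.0.3. The annotation release, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. The deposited table holds the authors' raw read counts per gene, whole numbers with no normalization, for 26688 genes and 15 libraries, with each gene's GRCm39 coordinates, biotype, and Gene Ontology and KEGG terms. Of these genes 18761 are protein-coding and 7913 are long noncoding RNA genes, and 906 had no read in any library. DESeq2 is named in the series design text as the authors' tool for differential expression; no result table of theirs was used here. Where 2 or more identifiers shared a symbol (15 symbols), the symbol stayed with the identifier of most reads. Genes with near-identical copies (Hspa1a and Hspa1b, Saa1 and Saa2, Bglap and Bglap2, the alpha-globin pair and the ribosomal protein genes) and genes that overlap a neighbour can exchange or lose reads in counting, so their values are uncertain.

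Libraries were grouped by their titles, and each count column carried the title of its library. No source says in so many words that each library came from a separate mouse, so the p-values measure the spread between these libraries. All mice being male per the labels, Xist and 4 Y-linked genes were checked in every library. Pairs of libraries within a group were compared by a chi-square per gene over genes with at least 20 reads in the pair, to look for a library present in duplicate.

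Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, genes passed filterByExpr (minimum count 10), the 3 groups were fitted together so that they shared an estimate of the spread, and each contrast was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment. This left 15770 genes tested and 10918 under the filter. In the text, "edgeR adjusted p" stands for the adjusted p of that test, and a gene is called higher or lower at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and the square root of F. The biological coefficient of variation was 27.8%. The procedure was tested on simulated counts for CIA versus healthy (15286 genes, 50 changed genes per fold size): it recovered 16% of changes of 1.5-fold, 62% of 2-fold, 82% of 3-fold and 96% of 4-fold, and called 4 unchanged genes.

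Gene lists (34 lists, 511 entries) for the tissue, the disease and cell types the sample could hold were fixed before the data were examined, as were the tests, the named-gene rule and the alternatives. Of these entries, 10 were not in the table under the symbol used and 43 lay under the filter. Lists with at least 5 tested members (33) were tested against all other genes with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. The keratinocyte list had too few tested members and is given only as a share of counts. Alternatives for lists were camera with a correlation estimated from the data, and fry, which asks whether the members of a list move on balance in a direction. The score of a list in a library is the mean log2 CPM (read counts scaled to an equal library size by TMM, prior count 2) of its tested members, and scores were compared with an exact two-sided permutation test of 5 libraries against 5 (252 assignments, smallest possible p 0.00794), adjusted over the lists. Gene Ontology and KEGG terms with 10 to 500 tested members were tested with Fisher's exact test, one-sided, against all tested genes.

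The named genes were set by a rule. It took, per contrast, the 5 largest rises and the 5 largest falls among called genes with an average log2 CPM of at least 1 and no overlap between the libraries of the 2 groups, leaving out provisional symbols, pseudogenes and antigen receptor segments. It took up to 3 called members per list with the lowest p (for a list without a called member, the member with the lowest p may be given as a value), and it always took Il1b, Il6, Tnf, Il17a, S100a8, Mmp3, Mmp13, Tnfsf11, Tnfrsf11b, Acp5 and Acta1. Il17a was not analysed here. Genes outside the rule are said to have been chosen after their values were seen.

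The reversal of the arthritis change under treatment was measured as the slope through the origin, sign reversed, of CIA+F20 minus CIA on CIA minus healthy log2 fold changes, over genes called in CIA versus healthy with at least a 2-fold change; a value of 1 is full return to healthy and 0 is none. Because both contrasts use the CIA libraries, these were split into 2 and 3 in all 20 ways, with calls and the arthritis change taken from the first part and the treatment change from the other. Data sets with no treatment effect were simulated 20 times for comparison, with each gene drawn independently, so they lack the variation that genes share between libraries. On simulated data with a reversal of 0.6 the split estimate gave 0.533 and the unsplit 0.587.

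The alternatives were other scalings (DESeq2 size factors, upper quartile), DESeq2 1.42.0 and limma voom with quality weights, other low-count filters, a fit of the 2 groups alone, the replicate number as a block, a 2-fold limit, the skeletal muscle list score as a covariate, removal of muscle, keratinocyte and erythroid genes, and omission of each library in turn. Leaving out healthy 3 and healthy 4 together, the erythroid list score as a covariate and thinning all libraries to the smallest total were chosen after seeing the data. The libraries used when each is omitted from the reversal estimate were first drawn at random and then, after seeing the values, replaced by a balanced set of assignments. Up to 100 other splits of the 10 libraries of each contrast were refitted.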

Results

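Joint tissue from the forelimbs of male DBA/1 mice was profiled by messenger RNA sequencing, with 5 libraries from non-immunized mice (healthy), 5 from mice with collagen-induced arthritis (CIA) and 5 from mice with the same arthritis treated with F20 (CIA+F20). Collagen-induced arthritis is an autoimmune joint disease raised by immunizing mice with type II collagen, the main collagen of cartilage. Mice entered the arthritic groups at an arthritis index over 5. F20, known here only by its code name, was given by mouth at 10 mg/kg once a day for 21 days. The libraries held between 18627303 (healthy 4) and 34247317 (healthy 5) counted reads. Group means were 28228605 ± 5905432 in healthy, 23412498 ± 2674023 in CIA and 29290693 ± 1939011 in CIA+F20 (SD, n = 5). No library had more than 10 Xist reads, and all 15 had over 100 reads of each of 4 Y-linked genes, as the male label requires. No label states that each library is a separate mouse, so the p-values measure the spread between libraries. Group values are means ± SD of 5 libraries in CPM, read counts scaled to an equal library size, and log2 fold changes carry their standard error.

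The tissue mix differed between the groups. Genes of the skeletal muscle list took 11.5 ± 0.472% of counts in healthy, 8.80 ± 2.36% in CIA and 10.9 ± 0.478% in CIA+F20 libraries. Erythroid genes, a sign of blood or marrow, took 0.0336 ± 0.0338%, 0.151 ± 0.117% and 0.0846 ± 0.0406%, and transcripts of the mitochondrial genome took 18.1 ± 1.02%, 15.5 ± 4.02% and 17.9 ± 1.3%. Keratinocyte genes, a sign of skin, took 0.00312 ± 0.00367%, 0.00154 ± 0.000704% and 0.00127 ± 0.000257%, too few tested members for a list test. CIA libraries differed most among themselves, with correlations of log2 CPM from 0.903 to 0.965 between them, against 0.962 to 0.989 within healthy and 0.976 to 0.985 within CIA+F20. These are correlations across genes, which are not independent replicates. The first principal component held 51.5% of the variance. It placed the healthy libraries between −67.6 and −22.6, the CIA+F20 libraries between −27.0 and 2.84 and the CIA libraries between 16.1 and 116. Healthy 3 had a mature neutrophil score of 2.99 where the next healthy library had 0.73, and healthy 4 had a T cell score of 2.24 where the next had −0.78.

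**Figure D1:**
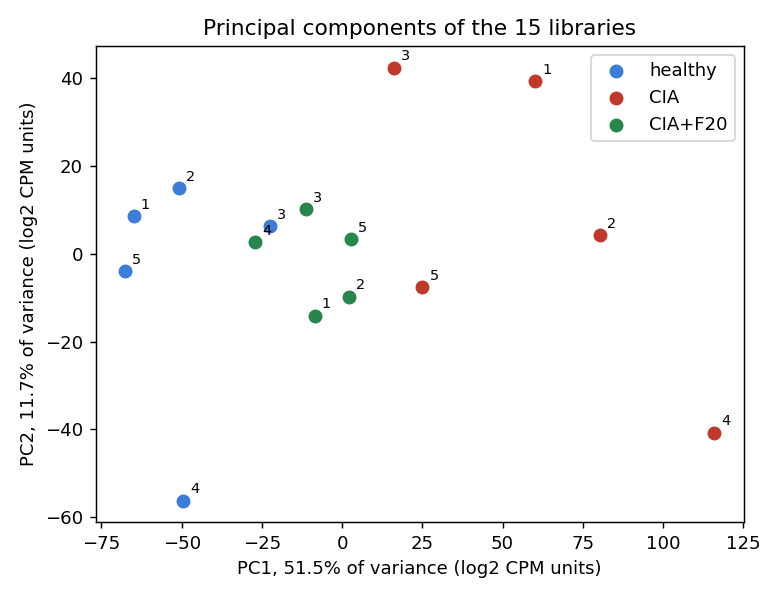
Principal components 1 and 2 of log2 CPM over the 15770 tested genes, with points for libraries labelled by replicate number and coloured by group. All 5 CIA libraries have a first component of 16.1 or more, and the CIA+F20 libraries, up to 2.84, lie between them and most healthy libraries.

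Arthritic joints were compared with healthy joints to find what the disease changes in the tissue. Genes of bone resorption, matrix breakdown, myeloid cells and inflammation were higher in CIA, and genes of mitochondrial respiration and muscle were lower. Acp5, the tartrate-resistant acid phosphatase of osteoclasts (ENSMUSG00000001348, GRCm39 chromosome 9, 22038023 to 22047007), rose from 8.82 ± 4.15 to 111 ± 60.9 CPM (log2 fold change 3.65 ± 0.57, edgeR adjusted p = 0.000401). The collagenase Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331) rose from 26.5 ± 13 to 436 ± 356 CPM (4.04 ± 0.66, edgeR adjusted p = 0.00052), and the stromelysin Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975) from 2.32 ± 1.21 to 76.7 ± 61.6 CPM (5.01 ± 0.81, edgeR adjusted p = 0.000491). The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46361422 to 46365124) and the neutrophil chemokine Cxcl5 (ENSMUSG00000029371, chromosome 5, 90907219 to 90909483) had the largest rises under the named-gene rule, 9.16 ± 1.81 and 7.98 ± 1.5, from almost no reads in healthy joints. In total 4094 genes were higher and 3081 lower in CIA, 45.5% of the 15770 tested, of which 1978 and 656 changed at least 2-fold. Of all tested genes, 3827 (24.3%, against 0.794% by chance) had no overlap between the libraries of the groups.

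Bone and matrix genes rose with the myeloid markers. In the osteoclast list 14 of 17 tested genes rose and none fell (camera adjusted p = 1.17e-09, and adjusted p = 0.204 with an estimated correlation), and the same 14 passed when adjusted over the list alone. Besides Acp5, these included Slc37a2 (3.17 ± 0.38), the proton pump subunit Tcirg1 (1.69 ± 0.19) and Snx10 (2.28 ± 0.24), which osteoclasts need to resorb bone. Tnfsf11, the osteoclast differentiation factor RANKL, rose by 2.45 ± 0.56 (edgeR adjusted p = 0.00328), while its decoy receptor Tnfrsf11b had a log2 fold change of 0.40 ± 0.70 (edgeR adjusted p = 0.663). Matrix-degrading proteases rose in 11 of 18 genes, also 11 adjusted over the list alone (camera adjusted p = 9.93e-06, and adjusted p = 0.204 with an estimated correlation). Among these were Mmp9 (4.28 ± 0.54), Mmp12 (6.37 ± 1.29) and cathepsin S, Ctss (3.03 ± 0.32). In the osteoblast and bone matrix list 6 of 16 genes rose and 1 fell, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.567 with an estimated correlation). Osteopontin, Spp1, rose by 2.59 ± 0.37, Ibsp by 2.65 ± 0.59 and Mepe by 2.93 ± 0.68. In the matrix and fibrosis list 7 of 18 rose, 6 adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.567 with an estimated correlation). They included tenascin C, Tnc (2.09 ± 0.32), and Tgfb1 (1.71 ± 0.30). The cartilage list (1 of 15 rose, Matn3, camera adjusted p = 0.529) and the synovial lining list (3 of 18 rose, 1 fell, camera adjusted p = 0.432) were not called, although the adhesion molecule Vcam1 rose by 2.08 ± 0.30 and Clic5, also of the lining list, fell by 1.01 ± 0.12. Which cells Clic5 came from was not tested. Healthy 4 had the lowest lining score of the healthy libraries (2.90) but 265 CPM of Clic5. The bone matrix list lost its call without healthy 4 (camera adjusted p = 0.0963), CIA 1 (0.0905) or CIA 3 (0.0888), and the matrix and fibrosis list without healthy 4 (0.061) or CIA 3 (0.0866).

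Myeloid and antigen-presenting cell markers were higher in CIA. All 16 macrophage genes rose, 16 also adjusted over the list alone (camera adjusted p = 1.13e-10, and adjusted p = 0.204 with an estimated correlation). Examples were the lysosomal glycoprotein Cd68 (2.73 ± 0.24; 4.33 ± 1.21 to 28.7 ± 10.1 CPM), Cd84 (2.84 ± 0.40) and Ms4a7 (3.52 ± 0.50). The list of resident lining macrophages was not called, with 2 of 10 genes higher (camera adjusted p = 0.529). All 14 mature neutrophil genes rose, 14 adjusted over the list alone (camera adjusted p = 3.64e-08, and adjusted p = 0.271 with an estimated correlation). S100a8 stood at 3.41 ± 0.76, Clec4d at 3.89 ± 0.54 and Clec4e at 4.25 ± 0.68. All 11 marrow granulocyte precursor genes rose, 11 adjusted over the list alone (camera adjusted p = 8.26e-06, and adjusted p = 0.348 with an estimated correlation). Members included Ms4a3 (3.64 ± 0.72), Fcnb and Chil3. Of the erythroid genes, 10 of 11 rose, 10 adjusted over the list alone (camera adjusted p = 0.00506, and adjusted p = 0.567 with an estimated correlation; Slc4a1 2.64 ± 0.84). Dendritic and antigen presentation genes rose in 11 of 15 and fell in 1, and in 12 and 1 adjusted over the list alone (camera adjusted p = 1.23e-06, and adjusted p = 0.204 with an estimated correlation). Among these were the class II genes H2-Aa (2.42 ± 0.29) and H2-Ab1 (2.33 ± 0.29) and the integrin Itgax (3.02 ± 0.36). B and plasma cell genes rose in 9 of 11, and in 10 with 1 lower adjusted over the list alone (camera adjusted p = 0.00301, and adjusted p = 0.515 with an estimated correlation). They included the immunoglobulin joining chain, Jchain (3.13 ± 0.64). The T cell list (2 of 8 rose, 1 fell, camera adjusted p = 0.664), whose mean change (−0.36) and list test differed in sign, and the mast cell list (2 of 7 rose, camera adjusted p = 0.389) were not called. The T cell result rests on healthy 4, without which the mean was 1.72 and the list was called higher in CIA (camera adjusted p = 0.0229).

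Inflammatory mediators and the pathways they use were higher as well. All 10 tested cytokine genes rose, 10 adjusted over the list alone (camera adjusted p = 0.000603, and adjusted p = 0.318 with an estimated correlation). Il1b stood at 4.01 ± 0.83 (0.563 ± 0.494 to 9.39 ± 10.2 CPM), Il6 at 5.44 ± 1.35, Tnf at 1.84 ± 0.58, Osm at 2.84 ± 0.54 and Lif at 2.70 ± 0.56. Chemokines rose in 15 of 17, 15 adjusted over the list alone (camera adjusted p = 6.37e-06, and adjusted p = 0.204 with an estimated correlation). Examples were Ccl8 (3.66 ± 0.45), Ccl9 (2.48 ± 0.35) and Cxcl9 (3.53 ± 0.51). All 19 interferon response genes rose, 19 adjusted over the list alone (camera adjusted p = 1.63e-10, and adjusted p = 0.204 with an estimated correlation). Members included Oasl2 (2.55 ± 0.31), Mx1 (2.98 ± 0.40) and Stat2 (1.04 ± 0.15), and the related antiviral enzyme Oas3 rose by 4.65 ± 0.79. STAT3 target and acute-phase genes rose in 14 of 16, 15 adjusted over the list alone (camera adjusted p = 0.000153, and adjusted p = 0.451 with an estimated correlation). NF-kB feedback genes rose in 10 of 13, 10 adjusted over the list alone (camera adjusted p = 9.93e-06, and adjusted p = 0.204 with an estimated correlation). Nfkbie stood at 2 ± 0.26 and Nfkbia, the inhibitor of the pathway, at 1.09 ± 0.15. Inflammasome genes rose in 12 of 13, 12 adjusted over the list alone (camera adjusted p = 4.11e-08, and adjusted p = 0.204 with an estimated correlation). Among these were the pore-forming Gsdmd (1.43 ± 0.20), the DNA sensor Aim2 (2.09 ± 0.26) and Il1rn, the natural antagonist of the interleukin 1 receptor (4.17 ± 0.47). Complement and Fc receptor genes rose in 11 of 15 and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 3.34e-05, and adjusted p = 0.291 with an estimated correlation). Fcer1g stood at 2.83 ± 0.40 and Fcgr4 at 4.6 ± 0.69. Eicosanoid synthesis genes rose in 7 of 12, 7 adjusted over the list alone (camera adjusted p = 0.00419, and adjusted p = 0.39 with an estimated correlation). Cell cycle genes rose in 15 of 16, 16 adjusted over the list alone (camera adjusted p = 9.85e-06, and adjusted p = 0.431 with an estimated correlation; Aurkb 2.77 ± 0.64). The NRF2 list was not called (6 of 12 rose, 1 fell, camera adjusted p = 0.0989), although heme oxygenase, Hmox1, rose by 3.68 ± 0.68, and it was called without CIA 1 (camera adjusted p = 0.0143) or CIA 3 (0.0364).

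**Figure D2:**
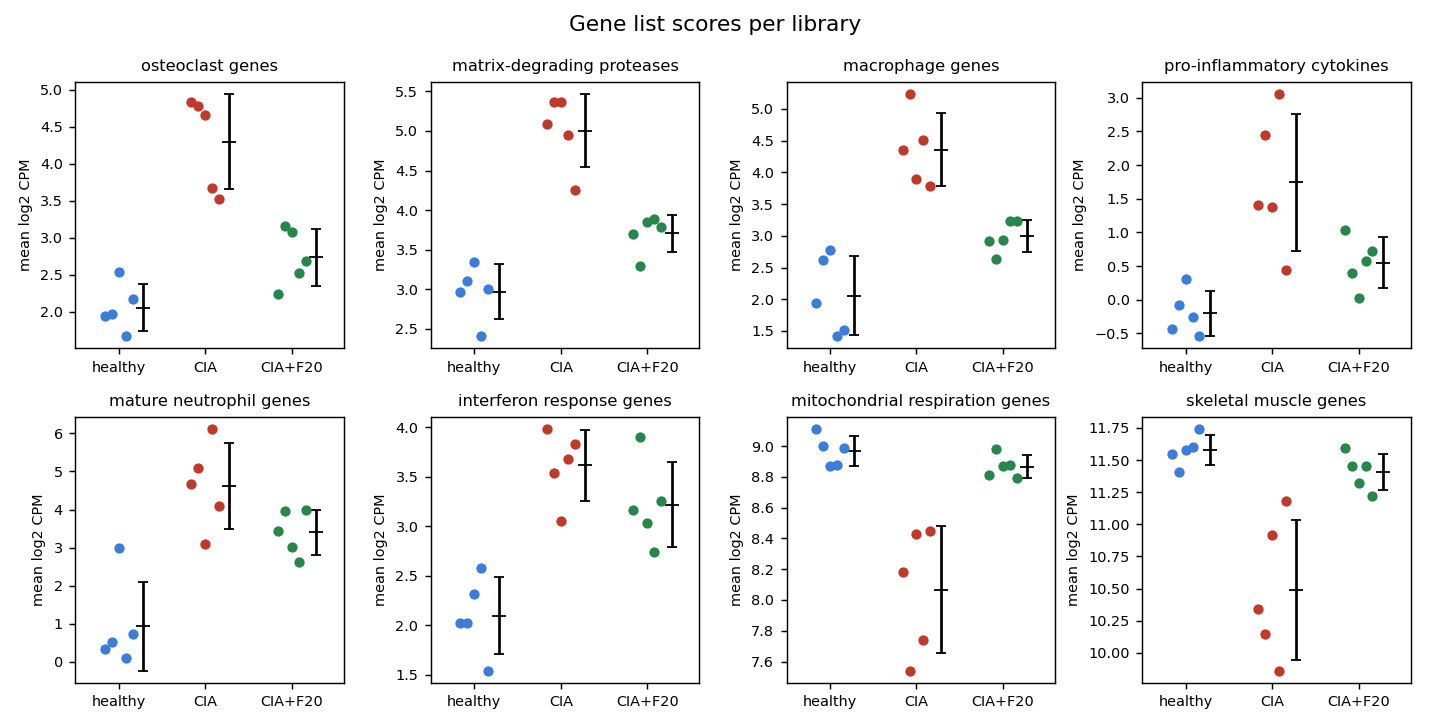
Score of 8 gene lists (mean log2 CPM of the tested members) in each library, with points for libraries and bars for the mean and SD of 5 libraries per group. The osteoclast score is 2.06 ± 0.32 in healthy, 4.30 ± 0.64 in CIA and 2.74 ± 0.39 in CIA+F20, while the interferon score is 2.09 ± 0.39, 3.62 ± 0.35 and 3.22 ± 0.43.

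Genes of energy metabolism and muscle were lower in CIA. All 14 mitochondrial respiration genes fell, 14 adjusted over the list alone (camera adjusted p = 2.98e-10, and adjusted p = 0.204 with an estimated correlation). They included Cox5a (−0.83 ± 0.11; 401 ± 23.8 to 226 ± 39.0 CPM), Cox6c (−0.73 ± 0.11) and Cyc1 (−0.98 ± 0.16). Skeletal muscle genes fell in 12 of 17, 12 adjusted over the list alone (camera adjusted p = 7.88e-06, and adjusted p = 0.271 with an estimated correlation). Examples were myoglobin, Mb (−1.22 ± 0.22), Eno3 (−1.26 ± 0.24), Myh2 (−1.27 ± 0.26) and the actin Acta1 (−0.69 ± 0.19). In the glycolysis and hypoxia list 8 of 16 genes fell and 4 rose, the same counts adjusted over the list alone (camera adjusted p = 0.0438, and adjusted p = 0.204 with an estimated correlation). Vegfa stood at −1.75 ± 0.21 and Pgk1 at −0.64 ± 0.13, and the list was not called without CIA 5 (camera adjusted p = 0.132). The largest falls under the named-gene rule were those of the lipid droplet protein Pnpla3 (−4.56 ± 0.62), Hspa1a (−4.25 ± 0.83), Rp1 (−4.19 ± 0.61), Ppp1r3c, a subunit that directs a phosphatase to glycogen (−4.13 ± 0.55; 767 ± 67.6 to 43.9 ± 20.6 CPM), and Hspa1b (−3.85 ± 0.82), the heat shock pair being near-identical copies whose reads are hard to assign. The clock list was not called as a whole (8 of 13 rose, 3 fell, camera adjusted p = 0.393), with Arntl at −3.56 ± 0.48, Clock at −1.03 ± 0.15 and Cry1 at −1.66 ± 0.28. The hour of sacrifice is not stated, so these clock changes cannot be told apart from a difference in hour. The endothelial (4 of 13 rose, 3 fell, camera adjusted p = 0.894), handling stress (4 of 14 rose, 5 fell, camera adjusted p = 0.396), adipocyte (0 of 11, camera adjusted p = 0.275, 0 also adjusted over the list alone) and Schwann cell lists (0 of 9, camera adjusted p = 0.613, 0 also adjusted over the list alone) were not called. The endothelial median and mean differed in sign, with Selp at 3.76 ± 0.62 and Kdr at −1.09 ± 0.19.

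**Figure D3:**
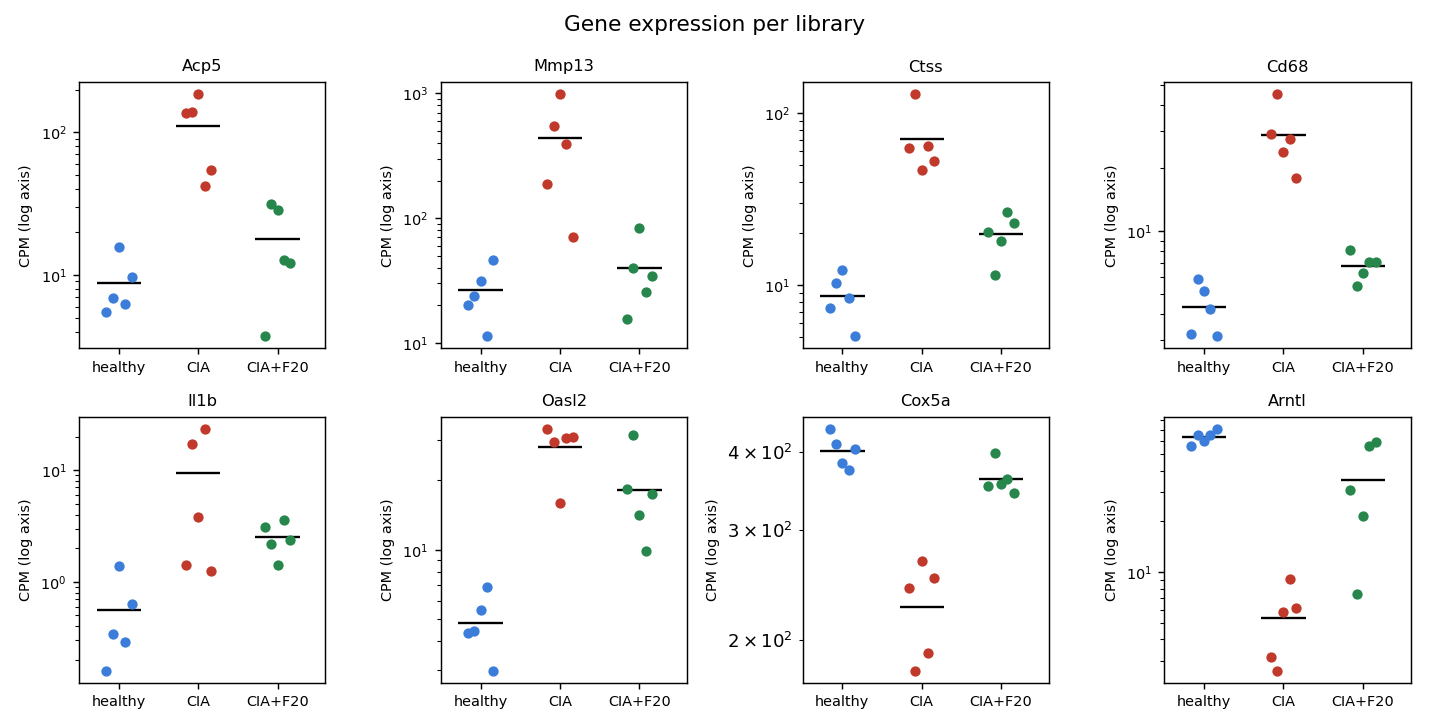
Expression of 8 genes in each library in CPM on log axes, with points for libraries and lines for the group mean. Acp5 averages 8.82 CPM in healthy, 111 in CIA and 17.7 in CIA+F20, and Cox5a averages 401, 226 and 362.

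Camera called 22 of the 33 tested lists in CIA versus healthy, 19 higher and 3 lower, and none with an estimated correlation (0 by that version, 23 by fry and 21 by the exact permutation test of the scores). The muscle list score moved with these changes: with that score as a covariate 19 genes were higher and 2 lower, and 14 lists were called. The score is a mean over genes and differs from the muscle share of counts. In CIA 3 and CIA 5 the share was 11.54% and 10.98%, within the healthy range (10.74 to 11.89%). Their scores of 10.92 and 11.18 lay below the healthy range (11.41 to 11.74). Under that covariate the osteoclast (mean log2 fold change 2.44 to 2.11) and protease lists (2.24 to 1.85) were still called near their size. Macrophage (2.36 to 1.19), chemokine (3.12 to 1.36), neutrophil (3.59 to 1.58), marrow precursor (3.66 to 1.61) and complement lists (1.69 to 0.65) shrank more but were still called. The same held for mitochondrial respiration (−0.84 to −0.26), inflammasome (2.07 to 0.96), NF-kB (1.1 to 0.59) and dendritic lists (1.49 to 0.91). Interferon genes stayed called near their size (1.55 to 1.43), and the called glycolysis list grew (−0.13 to −0.33). The clock list became called (0.75 to 1.29, camera adjusted p = 6.39e-05), and 9 lists lost their calls. The mean fell from 2.44 to 0.37 for cytokines, 2.66 to 0.24 for STAT3, 1.4 to 0.11 for eicosanoid, 2.2 to 0.44 for cell cycle, 2.11 to 1.01 for B cell and 2.15 to 0.56 for erythroid genes, and moved from −0.88 to 0.16 for muscle genes. It stayed near its size for matrix and fibrosis (1.23 to 1.17) and bone matrix genes (1.15 to 0.94). Single genes lost their calls, as with Acp5 (3.90 ± 0.96, edgeR adjusted p = 0.0984). With the erythroid list score as a covariate 1477 genes were higher and 1272 lower.

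Treated arthritic joints were compared with untreated arthritic joints to find what F20 changes in established disease. Osteoclast, protease and macrophage genes were lower under F20, and mitochondrial respiration and muscle genes were higher. Acp5 fell from 111 ± 60.9 to 17.7 ± 11.8 CPM (−2.65 ± 0.54, edgeR adjusted p = 0.00504), Mmp13 from 436 ± 356 to 39.6 ± 26.2 CPM (−3.46 ± 0.64, edgeR adjusted p = 0.00363) and Cd68 from 28.7 ± 10.1 to 6.82 ± 0.995 CPM (−2.07 ± 0.23, edgeR adjusted p = 0.00105). The largest falls under the named-gene rule included 3 further genes of the osteoclast and macrophage lineage, Atp6v0d2, a subunit of the proton pump (−3.26 ± 0.57), Slc37a2 (−2.50 ± 0.37) and Gpnmb (−2.38 ± 0.38), and the sodium-proton exchanger Slc9b2 (−3.33 ± 0.61). In total 2219 genes were higher and 2450 lower in CIA+F20 than in CIA, 29.6% of those tested, of which 388 and 840 changed at least 2-fold. Fitting these groups alone gave 1364 and 1310, and taking the replicate number as a block gave 1460 lower. Of all tested genes, 2145 (13.6%, against 0.794% by chance) had no overlap between the libraries of the groups.

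In the osteoclast list 13 of 17 genes fell, 13 adjusted over the list alone (camera adjusted p = 6.12e-09, and adjusted p = 0.269 with an estimated correlation). Members included Snx10 (−1.84 ± 0.24), Tcirg1 (−1.43 ± 0.19) and cathepsin K, Ctsk (−3.08 ± 0.58). RANKL, Tnfsf11, fell by 1.92 ± 0.54 (edgeR adjusted p = 0.0191) and Tnfrsf11b stood at −0.17 ± 0.70 (edgeR adjusted p = 0.87). Proteases fell in 9 of 18, 9 adjusted over the list alone (camera adjusted p = 5.91e-05, and adjusted p = 0.269 with an estimated correlation). Mmp3 stood at −2.93 ± 0.72 and Ctss at −1.83 ± 0.30. Macrophage genes fell in 14 of 16, 15 adjusted over the list alone (camera adjusted p = 4.88e-08, and adjusted p = 0.269 with an estimated correlation). Ms4a7 stood at −2.15 ± 0.46. Inflammasome genes fell in 9 of 13, 12 adjusted over the list alone (camera adjusted p = 5.91e-05, and adjusted p = 0.269 with an estimated correlation). Casp1 stood at −1.28 ± 0.29, Gsdmd at −0.97 ± 0.19 and Il1rn at −2.10 ± 0.41. NF-kB feedback genes fell in 7 of 13, 9 adjusted over the list alone (camera adjusted p = 8.31e-05, and adjusted p = 0.269 with an estimated correlation). Nfkbia stood at −0.83 ± 0.15, Nfkbiz at −1.50 ± 0.29 and Traf1 at −1.49 ± 0.29. Dendritic and antigen presentation genes fell in 8 of 15 and rose in 1, 10 and 1 adjusted over the list alone (camera adjusted p = 0.000617, and adjusted p = 0.269 with an estimated correlation). Itgax stood at −2.11 ± 0.34 and H2-Ab1 at −1.25 ± 0.28. Matrix and fibrosis genes fell in 6 of 18, 6 adjusted over the list alone (camera adjusted p = 0.00388, and adjusted p = 0.636 with an estimated correlation). Among these were the collagen cross-linking enzyme Lox (−3.65 ± 0.85) and Tnc (−1.62 ± 0.31). Bone matrix genes fell in 3 of 16 and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.0474, and adjusted p = 0.684 with an estimated correlation). Spp1 stood at −2.30 ± 0.36. This list lost its call without CIA 1 (camera adjusted p = 0.175), CIA 3 (0.146) or CIA+F20 1 (0.0802), 3 (0.0578) or 4 (0.0839).

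Other inflammatory lists were lower as well. Cytokines fell in 5 of 10, 8 adjusted over the list alone (camera adjusted p = 0.00352, and adjusted p = 0.564 with an estimated correlation). Lif stood at −2.72 ± 0.56 and Il11 at −2.34 ± 0.63. Il1b (−1.89 ± 0.73, edgeR adjusted p = 0.0636), Il6 (−2.64 ± 1.09, edgeR adjusted p = 0.0772) and Tnf (−1.08 ± 0.54, edgeR adjusted p = 0.138) did not pass. Chemokines fell in 8 of 17, 8 adjusted over the list alone (camera adjusted p = 0.00495, and adjusted p = 0.599 with an estimated correlation). Ccl9 stood at −1.58 ± 0.34 and Cxcl2 at −2.72 ± 0.67. STAT3 target genes fell in 11 of 16, 13 adjusted over the list alone (camera adjusted p = 0.000684, and adjusted p = 0.636 with an estimated correlation). Complement and Fc receptor genes fell in 8 of 15 and rose in 1, C7 (2.07 ± 0.53), the same adjusted over the list alone (camera adjusted p = 0.00635, and adjusted p = 0.636 with an estimated correlation). Mature neutrophil genes fell in 3 of 14, 3 adjusted over the list alone (camera adjusted p = 0.00479, and adjusted p = 0.684 with an estimated correlation). S100a8 stood at −1.45 ± 0.70 (edgeR adjusted p = 0.125). The marrow precursor (0 of 11, 0 adjusted over the list alone, camera adjusted p = 0.0474, and adjusted p = 0.713 with an estimated correlation) and eicosanoid lists (3 of 12 fell, 3 adjusted over the list alone, camera adjusted p = 0.0273, and adjusted p = 0.636 with an estimated correlation) passed narrowly. So did the interferon list (1 of 19 fell, 0 adjusted over the list alone, camera adjusted p = 0.0273, and adjusted p = 0.71 with an estimated correlation). Irf1 stood at −0.45 ± 0.14. The cell cycle list also passed (1 of 16 fell, 0 adjusted over the list alone, camera adjusted p = 0.00218, and adjusted p = 0.684 with an estimated correlation). The marrow precursor list lost its call without CIA 1, 4 or 5 or CIA+F20 1, 3 or 4 (camera adjusted p from 0.0639 to 0.248). The eicosanoid list lost it without CIA 1 or 4 or CIA+F20 1 or 3 (0.0639 to 0.113), and the interferon list without CIA 1 or 5 or CIA+F20 3 or 4 (0.0566 to 0.121).

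All 14 mitochondrial respiration genes rose under F20, 14 adjusted over the list alone (camera adjusted p = 3.43e-11, and adjusted p = 0.269 with an estimated correlation). Cox5a stood at 0.68 ± 0.11, Cyc1 at 0.89 ± 0.16 and Sdhb at 0.90 ± 0.17. Muscle genes rose in 5 of 17, 7 adjusted over the list alone (camera adjusted p = 4.07e-05, and adjusted p = 0.401 with an estimated correlation). Myh2 stood at 1.29 ± 0.26 and Mb at 1.10 ± 0.22. Glycolysis and hypoxia genes rose in 7 of 16 and fell in 1, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0474, and adjusted p = 0.269 with an estimated correlation). Vegfa stood at 1.40 ± 0.21, and the list lost its call without CIA 1 or 5 or CIA+F20 1, 4 or 5 (camera adjusted p from 0.0503 to 0.182). Among the largest rises under the named-gene rule were Pnpla3 (3.79 ± 0.62), Ppp1r3c (3.22 ± 0.53), Zp2 (2.63 ± 0.44), Lgi1 (2.45 ± 0.44) and Vwa3a (2.43 ± 0.38). Arntl rose by 2.70 ± 0.47 and Clock by 0.83 ± 0.15, and Clic5 by 0.80 ± 0.12. The treated libraries were split for Arntl, with 56.3 and 59.1 CPM in CIA+F20 4 and 5 and 30.6, 7.40 and 21.6 CPM in CIA+F20 1, 2 and 3. Ppp1r3c was split likewise, with 720 and 805 CPM against 269, 120 and 127 CPM. The cause of the split was not tested, so the rises of Arntl and Ppp1r3c cannot be assigned to F20 alone. Not called were the B cell (camera adjusted p = 0.294), T cell (0.753), mast cell (0.601), endothelial (0.919), resident lining macrophage (0.663), synovial lining (0.188), cartilage (0.753), NRF2 (0.0881), adipocyte (0.052), erythroid (0.305), Schwann cell (0.892), handling stress (0.753) and clock (0.682) lists. The NRF2 list was called lower without CIA 1 (0.00921) or CIA 3 (0.0281), and the adipocyte list higher without CIA 5 or CIA+F20 1, 4 or 5 (0.0117 to 0.0463).

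Camera called 20 lists in CIA+F20 versus CIA, 3 higher and 17 lower, and 0 with an estimated correlation; fry called 10 and the exact permutation test 9. The mean muscle share and the muscle list score rose with treatment. With that score as a covariate edgeR called 0 genes higher and 0 lower (0 by that test, against 2219 and 2450 without it), and camera called 6 lists. Standard errors of called genes grew 1.33 times and folds shrank to a slope of 0.383, but unevenly. Acp5 (−2.65 to −2.86), Mmp13 (−3.46 to −3.41) and Slc37a2 (−2.50 to −2.45) kept their size. Cd68 shrank (−2.07 to −1.40) and Il1b turned without a call (−1.89 to 1.06 ± 1.03, edgeR adjusted p = 0.814). The osteoclast list (mean log2 fold change −1.71 to −1.44) and the proteases (−1.52 to −1.17) kept their calls under that covariate near their size. Macrophage (−1.50 to −0.49) and mitochondrial respiration lists (0.74 to 0.25) kept theirs but shrank, and the glycolysis list kept its call and grew (0.16 to 0.33). The clock list became called (−0.15 to −0.60, camera adjusted p = 0.000583). Inflammasome (−1.14 to −0.20, camera adjusted p = 0.279), dendritic (−0.86 to −0.36, 0.113) and NF-kB lists (−0.77 to −0.33, 0.0565) shrank and lost their calls. The cytokine (0.27, camera adjusted p = 0.571), chemokine (0.19, 0.736), neutrophil (0.23, 0.401) and STAT3 lists (0.59, 0.133) turned positive without a call. Without CIA 2 the counts were 1478 higher and 1405 lower, and the lower count was 1614 without CIA 4 and 1471 without CIA+F20 4.

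How far treatment moved arthritic joints back towards healthy was measured over genes changed at least 2-fold in CIA. The reversal was 0.514 (median of 20 assignments, 0.189 to 0.799), where 1 is a full return to healthy, with the CIA libraries of the disease and treatment contrasts kept apart; with no treatment effect, simulations gave −0.00828. With all CIA libraries in both contrasts it was 0.581 over 2634 genes, against 0.045 in simulations. Of the genes called in CIA versus healthy, 4315 (60.1%) were called with the opposite sign in CIA+F20 versus CIA and 0 with the same sign. The overlap expected for independent lists is 1070, and the highest count in 20 simulations without a treatment effect was 1. All these simulations drew each gene independently, without the variation that genes share between libraries. Their values for no treatment effect are therefore too narrow to serve as a chance range. Other splits of the CIA and CIA+F20 libraries called up to 2931 genes. The share of the CIA change that remained under F20 was 11.5 ± 8.24% for mitochondrial respiration, 30.3 ± 17.2% for osteoclast genes, 36.2 ± 11.7% for proteases and 40.8 ± 11% for macrophage genes. It was 67.0 ± 16.2% for mature neutrophil, 72.2 ± 18% for marrow precursor, 73.7 ± 28.2% for interferon response and 75.3 ± 29.6% for B cell genes (SD, n = 5 libraries). With the erythroid score as a covariate the rise in CIA shrank for neutrophil (3.59 to 2.13), marrow precursor (3.66 to 1.85) and B cell genes (2.11 to 0.71). It shrank less for interferon genes (1.55 to 1.25). A share of blood or marrow in what remained for the first 3 lists is therefore left open. The overlap counts rest on shared CIA libraries. With these split the count of opposite sign ran from 0 to 3526 over the assignments (median 1578, 424 expected for independent lists), and without CIA 2 the unsplit count was 2771.

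**Figure D4:**
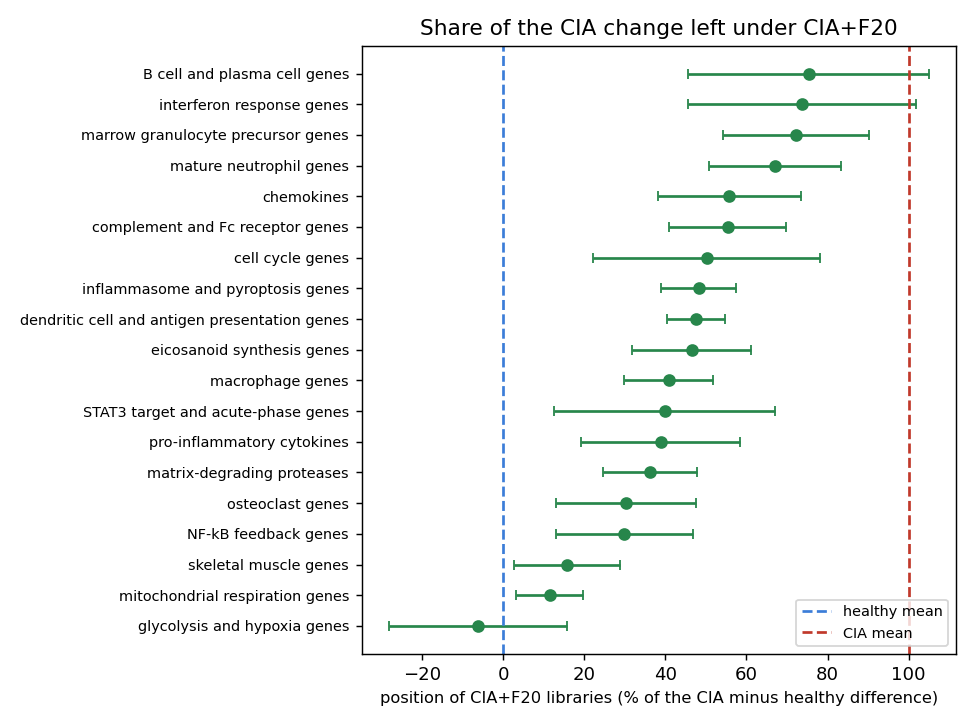
Position of the CIA+F20 libraries on the scale from the healthy mean (0%) to the CIA mean (100%) for the 19 gene lists called in CIA versus healthy by both camera and the exact test, with points for the mean and bars for the SD of 5 libraries. Mitochondrial respiration genes lie at 11.5%, osteoclast genes at 30.3% and interferon response genes at 73.7%.

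Treated joints were compared with healthy joints to find what still differs under treatment. edgeR called 0 genes higher and 0 lower, with a smallest adjusted p of 0.127; at an unadjusted p under 0.05 there were 1388 genes (1043 higher, 345 lower) where 788 are expected by chance. DESeq2 called 108 higher and 10 lower, limma voom 94 and 13, and edgeR 105 and 2 without healthy 3. Genes whose libraries did not overlap numbered 512 (3.25%, against 0.794% by chance). Interferon response genes had the smallest camera p of the lists: 18 of 19 were higher when adjusted over the list alone, and the list score was 3.22 ± 0.43 in CIA+F20 and 2.09 ± 0.39 in healthy (exact permutation p = 0.00794, the smallest possible, adjusted 0.0476, camera adjusted p = 1.43e-33, and adjusted p = 0.0692 with an estimated correlation). Oasl2 (ENSMUSG00000029561, chromosome 5, 115034997 to 115050295) had 18.3 ± 8.12 CPM in CIA+F20 and 4.82 ± 1.45 in healthy joints (1.93 ± 0.30, edgeR adjusted p = 0.127). Adjusted over the list alone, 13 of 14 mature neutrophil genes (camera adjusted p = 5.44e-23, and adjusted p = 0.0692 with an estimated correlation), 11 of 11 marrow precursor genes (camera adjusted p = 6.93e-18, and adjusted p = 0.08 with an estimated correlation) and 8 of 17 chemokines (camera adjusted p = 9.88e-12, and adjusted p = 0.0692 with an estimated correlation) were also higher. So were 7 of 16 macrophage genes (camera adjusted p = 1.07e-10, and adjusted p = 0.162 with an estimated correlation) and 6 of 11 B cell genes (camera adjusted p = 1.14e-08, and adjusted p = 0.195 with an estimated correlation). The erythroid list moved with them (mean log2 fold change 1.3, 0 of 11 genes by edgeR and 0 adjusted over the list alone, camera adjusted p = 1.85e-07, and adjusted p = 0.279 with an estimated correlation), which leaves a larger share of blood or marrow open as part of these differences. With the erythroid score as a covariate 14 lists were called, 12 of them among the 20 called without it, and the neutrophil (mean 2.11 to 1.28), marrow precursor (2.22 to 1.31) and B cell lists (1.38 to 0.56) shrank but kept their calls. Without healthy 4 the T cell list was also called higher (mean 1.31, camera adjusted p = 8.42e-07). Among single genes that edgeR did not call, Cxcl9 stood at 2.81 ± 0.52 (edgeR adjusted p = 0.16), Il1rn at 2.08 ± 0.45 and Cd74 at 1.20 ± 0.26 (edgeR adjusted p = 0.199 each), Mmp9 at 2.15 ± 0.50 (edgeR adjusted p = 0.267), Acp5 at 1.00 ± 0.53 (edgeR adjusted p = 0.623) and Mmp13 at 0.58 ± 0.59 (edgeR adjusted p = 0.883). Camera called 20 lists, 17 higher and 3 lower (mitochondrial respiration, muscle and handling stress), and 0 with an estimated correlation; fry called 6 and the exact permutation test 11. Mitochondrial respiration lost its call without healthy 1 (camera adjusted p = 0.0856) or CIA+F20 5 (0.0548), and handling stress without healthy 4 (0.0608).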

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

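Of the tests in this part, the comparison of the macrophage list with 4 other tissue lists, the B cell score of healthy 4, the tests of carried-over reads, the erythroid covariate, the thinning, the gene sets of the clock arms and of thymic stroma, and the splits counted at an unadjusted p were chosen after the data or results were seen; the others were set before. In each of 153 groups of 5 values, the end library was compared with its nearest neighbour, and its gap exceeded Dixon's 95% limit of 0.71 of the group's range in 12 groups. Chance alone gives this in about 1 in 20 groups.

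Among healthy libraries, healthy 3 stood apart with a mature neutrophil score of 2.99 (nearest other 0.73), 86.9 CPM of S100a8 (nearest 12.2) and a keratinocyte share of 0.00966% (nearest 0.00199%). Healthy 4 had a T cell score of 2.24 (nearest −0.78). Healthy 2 had the lowest muscle share, 10.7% of counts (nearest 11.6%), and 25397 CPM of Acta1 (nearest 28207). Healthy 5 had 1.52 CPM of Tnfsf11 (nearest 0.38). Among CIA libraries, CIA 5 had an endothelial score of 4.24 (nearest 4.96). Among CIA+F20 libraries, CIA+F20 1 had a mast cell score of 0.30 (nearest 0.78), an NRF2 score of 5.04 (nearest 4.78) and 3.16 CPM of Il6 (nearest 0.44), and CIA+F20 2 had 0.86 CPM of Mmp3 (nearest 10.7).

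The higher inflammatory, osteoclast and protease genes in CIA came with less muscle, more erythroid signal and fewer reads per library. A smaller muscle share alone would raise tissues lying wholly outside muscle alike, but endothelial and nerve genes can also come from within muscle. The macrophage list stood 2.07 above the pooled endothelial, Schwann, cartilage and lining macrophage lists in median log2 fold change (2.46 over 16 genes, 0.39 over 47). The permutation over genes gave p = 4e-05, but it treats genes as independent, and estimated correlations within these lists ran from 0.458 to 0.949. That p is therefore too small and does not measure the spread between libraries. The sizes depend on the lists pooled. Among lists left out, the median was −0.23 for adipocyte, 0.83 for synovial lining, 1.02 for matrix and fibrosis and 1.27 for bone matrix genes. The comparison therefore cannot decide whether the muscle share is part of the rise. Marrow carried over is argued against for osteoclast and protease genes, whose lists stayed called with the erythroid score as a covariate (osteoclast 2.44 to 2.36, proteases 2.24 to 2.21). Neutrophil (3.59 to 2.13) and marrow precursor genes (3.66 to 1.85) shrank there, and B cell (2.11 to 0.71) and eicosanoid lists (1.4 to 0.68) shrank and lost their calls. The bone matrix list lost its call with much of its size left (1.15 to 0.83, camera adjusted p = 0.0897). Fewer reads are argued against by the 3870 genes still higher when all libraries were thinned to the smallest total. With the muscle score as a covariate standard errors grew 1.52 times and folds shrank to a slope of 0.439, so calls ended for Acp5 (3.65 ± 0.57 to 3.90 ± 0.96) by its spread and for Il1b (4.01 ± 0.83 to 0.66 ± 1.11) by its size. Cytokine (2.44 to 0.37), STAT3, eicosanoid, cell cycle, B cell and erythroid lists shrank and lost their calls, while matrix and fibrosis (1.23 to 1.17) and bone matrix (1.15 to 0.94) lost theirs near the same size. Whether the shrunken lists follow disease or the muscle score stays open, since more severe joints may lose more muscle. Arthritis itself remains an untested biological explanation.

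Healthy 4 held T-lineage transcripts that other healthy libraries nearly lacked, such as Cd8a (334 counts, at most 3 elsewhere), Ptcra (165, at most 2) and Scart1 (1185, at most 8). Thymus tissue is argued against by Cd4 at 4.79% of Cd8a counts. Of its stroma genes 1 of 5 exceeded the other healthy libraries, but these cannot decide, being near the floor. Psmb11, Foxn1 and Tbata had 0 counts in healthy 4 and Prss16 had 2, against at most 1, 1, 3 and 6 in other healthy libraries. Rag1 (92 counts, at most 38 elsewhere), Il2ra (498, at most 68) and Lef1 (400, at most 20) were also higher in healthy 4, and Dntt was lower (2, up to 21). Lymph node is argued against by a B cell score of −1.22, below the other healthy libraries (−0.87 to 1.00). CIA+F20 4 was the highest CIA+F20 library in 30 of 48 genes that stood out in healthy 4 (62.5%, 20% by chance), as reads carried over from healthy 4 would give. As the whole source there they are argued against by a joint test of 26 of these genes against one ratio (chi-square with simulated p = 1e-05 with the spread between libraries included, 0.001 without Scart1), since Scart1 had 8 counts where 6.21% predicts 73.6, but a part of the signal cannot be told apart from carried-over reads, and no biological explanation was tested.

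Clock genes, of which Nfil3, Ciart and Per3 were chosen after their values were seen, moved in opposite arms in CIA: Arntl, Clock, Nfil3 and Cry1 fell (4 of 5 genes, median −1.66), and Dbp, Ciart, Per3 and others rose (9 of 10, median 1.59). Loss of muscle would lower both arms, so the rise of 1.59 argues against it, and with the muscle covariate the clock list became called (mean 0.75 to 1.29). Another hour of sacrifice in the CIA group would move the arms apart as seen, with −1.66 in the arm of Arntl, but it cannot be told apart from an effect of arthritis because no label gives the hour. Within CIA+F20 the libraries were split. CIA+F20 4 and 5 had 9.73 and 8.45 CPM of Dbp, against 49.2, 172 and 97.3 CPM in CIA+F20 1, 2 and 3. Healthy libraries had 8.71 to 10.2 CPM. Arntl was split likewise (56.3 and 59.1 against 30.6, 7.40 and 21.6 CPM). So was Cry1 (41.6 and 39.16 against 16.03, 15.18 and 14.18 CPM), but not Per2 (13.7 and 9.13 against 6.21, 26.63 and 11.28 CPM). Another hour within the treated group could give such a split, but it cannot be told apart from an effect of F20.

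Whether chance placed the libraries was tested by refitting 100 of the 126 splits of the 10 libraries of each contrast. The real split gave the most called genes in CIA versus healthy (7175, highest other 3251; 1 of 100 as large) and in CIA+F20 versus CIA (4669, highest other 2931; 1 of 100). This share is the smallest that 100 splits can give, so a chance placement of the libraries is unlikely there but not excluded. The splits cannot address differences in handling or hour that run along with the groups. In CIA+F20 versus healthy the real split called 0 genes with edgeR (1388 at an unadjusted p under 0.05; 108 higher and 10 lower by DESeq2, 94 and 13 by limma voom) and all 100 splits gave as many, highest other 0, which holds for any count of 0 and says nothing about chance. Counted at an unadjusted p under 0.05, 3 of 100 splits gave as many as the real 1388, highest other 1626. That share is under 0.05, but the count was picked after the 0 was seen and other splits exceed it, so chance is not firmly excluded.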

How the results depend on the processing

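The erythroid covariate, thinning, and healthy 3 and 4 left out together were chosen after seeing the data, as was the balanced set of assignments behind the reversal without each library. All others were set before. Apart from the muscle covariate, named genes were labelled the same in 4956 of 5230 comparisons with an alternative (227 weaker, 46 stronger, 1 turned) and lists in 1068 of 1182 (103, 10 and 1). A gene or list counted as turned only where its direction changed and the main fit or the alternative called it. A change of direction that neither called counted as the same. Where no cause is given below, the cause was not tested.

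A 2-fold limit left 1978 higher and 656 lower genes in CIA versus healthy and 388 and 840 in CIA+F20 versus CIA, as its construction requires. The erythroid covariate gave 1477 and 1272 genes in CIA versus healthy. In CIA+F20 versus CIA, fitting those groups alone gave 1364 and 1310, and the replicate block 1460 lower genes. In CIA+F20 versus healthy DESeq2 called 108 and 10 and limma voom 94 and 13. Lists called with an estimated correlation were 0 in each contrast (22, 20 and 20 with the preset value), and fry called 10 in CIA+F20 versus CIA and 6 in CIA+F20 versus healthy. Splitting the CIA libraries left 1578 opposite calls, with fewer libraries on each side.

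The muscle covariate left 19 higher and 2 lower genes in CIA versus healthy (11 and 2 of them called without it), 0 and 0 in CIA+F20 versus CIA by edgeR, and 14 and 6 lists. It turned lists in CIA versus healthy (STAT3 0.24 and eicosanoid 0.11, by the direction of the list test) and in CIA+F20 versus CIA (cytokines 0.27, chemokines 0.19, neutrophil 0.23, marrow precursor 0.30, STAT3 0.59, complement 0.05, eicosanoid 0.19, cell cycle 0.22, muscle −0.16). Genes that turned were Pdpn (−0.60), Ms4a2 (−0.17) and Acta1 (0.03) in CIA versus healthy. In CIA+F20 versus CIA they were Csf1 (0.04), Pdpn (0.71), Cx3cr1 (0.10), Trem1 (0.29), Serpina3n (0.79), Saa1 (0.97), Cfp (0.07), Pla2g4a (0.17), Ptgs2 (0.36), Alox5ap (0.55), Gsta4 (−0.18), Bnip3 (−0.01), Tpx2 (0.02), Ier3 (0.05), Ier2 (0.03) and Acta1 (−0.05). The erythroid covariate turned its own list (−0.04) and Ms4a2 (−0.50) in CIA versus healthy. No list or gene that the muscle covariate turned was called under it. The muscle score fell with disease, so the covariate removes part of the group difference by construction.

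Leaving out each library in turn gave 3420 to 4430 higher and 2560 to 3621 lower genes in CIA versus healthy, 1478 to 3007 and 1405 to 3208 in CIA+F20 versus CIA, and 0 to 105 and 0 to 2 in CIA+F20 versus healthy. Moves of over 1.5 times came without CIA 2 (1478, 1405 and an overlap of 2771), CIA 4 (1614 lower), CIA+F20 4 (1471 lower) and healthy 3 (105 and 2). Lists called ranged from 21 to 22, 16 to 20 and 20 to 22, with the T cell list called higher than healthy in CIA (1.72) and CIA+F20 (1.31) without healthy 4, the overlap from 2771 to 5682, and the reversal from 0.367 to 0.573 (0.49 with all libraries in the same 5 assignments). Libraries of equal number were not more alike (correlations across genes −0.395 to 0.243 in CIA versus healthy, −0.382 to 0.22 in CIA+F20 versus CIA, −0.206 to 0.015 in CIA+F20 versus healthy), and the best match carried the same number for 2, 1 and 0 of 5 libraries. The unpaired test had been set beforehand. In simulated counts 16% of 1.5-fold changes were called, so small changes can be missed.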

Other observations

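The lists of fibre types and of denervation and atrophy genes were written after a first look at the data. The tests of list differences here were chosen after the results were seen, so their p-values are not adjusted for that choice. Muscle genes fell unevenly in CIA. Of 10 slow-twitch fibre genes 9 fell (median −2.00), such as the slow troponins Tnnc1 (−2.58 ± 0.73) and Tnni1 (−2.24 ± 0.67), and of 11 fast-twitch genes 5 fell (median −0.63), Tnnc2 being left out for its few reads. The slow minus fast score changed by −1.93 in CIA (exact permutation p = 0.0238) and by 2.04 with F20 (exact permutation p = 0.0238), while CIA 5 (−2.87) lay within the healthy range (−4.11 to −2.54). Of 15 denervation and atrophy genes 9 rose in CIA (median 1.43) and 6 fell with F20 (median −1.13). Whether fibres were lost, expressed these genes less or were trimmed differently was not tested.

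Gene Ontology terms showed ribosomes and mitochondria moving apart. No fixed list covered ribosomes. The mitochondrial terms and KEGG osteoclast differentiation share their subject with fixed lists and are no separate evidence. Cytosolic ribosome genes were higher in CIA in 51 of 70 (Fisher's exact test, adjusted p = 2.76e-13) and lower with F20 in 54 of 70 (adjusted p = 4.9e-27). Genes of the mitochondrial inner membrane were lower in CIA in 296 of 434 (adjusted p = 6.68e-108) and higher with F20 in 258 (adjusted p = 1.75e-107), and mitochondrial translation was lower in 79 of 93 and higher in 68. The direction held under DESeq2 and upper-quartile scaling and with muscle, keratinocyte and erythroid genes removed (49 to 51 ribosomal genes higher in CIA). With the erythroid covariate 20 of 70 ribosomal genes were higher and 191 of 434 mitochondrial genes lower in CIA, with medians of about the same size (0.39 to 0.42 and −0.47 to −0.41). With the muscle covariate 0 of 70 ribosomal and 0 of 434 mitochondrial genes were called by edgeR, and the medians shrank. They went from 0.39 to 0.13 and from −0.47 to −0.16 in CIA, and from −0.42 to −0.22 and from 0.41 to 0.13 with F20. KEGG osteoclast differentiation was higher in CIA in 62 of 101 genes (adjusted p = 2.81e-12) and lysosome in 66 of 124 (adjusted p = 1.69e-09). Fisher's exact test treats genes as independent, while the estimated correlation within the mitochondrial respiration list was 0.835 in CIA versus healthy. The p-values of these terms are therefore too small and do not measure the spread between libraries.

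The interferon list fell less under F20 than the osteoclast list. The score changed by −1.56 for osteoclast genes and by −0.40 for interferon genes, a difference of −1.16 (exact permutation p = 0.0397 over 252 assignments), and the share left was larger for interferon genes in 5 of 5 CIA+F20 libraries. In CIA the osteoclast score had risen by 2.24 and the interferon score by 1.52. An equal share of reversal would thus also give a negative difference, and that p does not test the share left. The shares of the 5 libraries all use the same healthy and CIA means. The pair was picked after the list results, and no test here addresses where F20 acts.

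The CIA libraries were unlike one another. Il6 was 6.54 CPM in CIA 2 and 18.6 CPM in CIA 4, against 0.28, 1.04 and 0.18 CPM in CIA 1, 3 and 5. Saa3 ran from 0.96 CPM in CIA 5 to 127 CPM in CIA 2, while Acp5 was highest in CIA 3 (185 CPM) and lowest in CIA 4 (41.8 CPM). The fast troponin gene Tnnc2 had 3 to 18 counts per library where its partner Tnnt3 had 150050 to 377152, and Tnnc2 spans 2807 bases of chromosome 2, of which 1662 overlap Ube2c on the opposite strand.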
